A study of Caenorhabditis elegans with 9 samples.

How the data were processed

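RNA was extracted with TRIzol from whole L4 animals and sequenced as paired ends after library preparation with an NEBNext Ultra kit, per the labels' protocols. Per the submitters' processing notes and the labels, transcripts of a WormBase reference (release WS245) were quantified by kallisto (version 0.46.0), after demultiplexing by bcl2fastq. Whether the library kit kept strand is not given in the sources used here, so reads of a gene and of an antisense or overlapping neighbour cannot be told apart. The authors deposited 1 table per sample with the estimated counts of 30939 transcripts, which are fractional and not normalized, per the file headers and the values. The transcript lengths and effective lengths in these tables, also deposited, served only to compute TPM for an alternative. The authors also deposited a series table of CPM per gene, with 20306 entries and each column scaled to one total, per the values. Of these, 276 were named NA and held 0 in each library and 10 carried a bare number as name. By symbol 19013 were matched, and within a tolerance of 1%, 99.7% of compared genes had the same CPM as sums of the estimated counts.

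For each gene the estimated counts of its transcripts were summed and rounded to whole numbers, giving 20444 genes. Of these, 20165 were matched to the WBcel235 annotation for symbols and coordinates, and 279 kept their sequence name, holding 0.165% of the counts. Kallisto divides reads between near-identical transcripts by its model, so values of close paralogs are uncertain, and identical copies receive equal parts. Library totals ran from 14461993 to 16659895 counts. The 10 most abundant genes held 4.18% to 4.92% of counts, and 14065 to 14467 genes had at least 10 counts in a library.

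Samples were grouped by genotype and maternal treatment from the labels, with 3 libraries in each of 3 groups. Tests used edgeR 4.0.16 in R 4.3.3 with filterByExpr, TMM scaling, robust quasi-likelihood fits over all 9 libraries and Benjamini-Hochberg adjustment over the 14795 genes tested, with calls at an adjusted p under 0.05. CPM values are TMM-normalised, and the SE of a log2 fold change is its size divided by the square root of the F statistic. 38 gene lists, written from textbook knowledge before the data were examined, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. An estimated correlation and fry were alternatives. fry tests whether a list's genes move one way on balance and does not compare them with other genes. Genes named were fixed by a rule before the data were examined: *nhr-114*; 12 genes of B12, one-carbon and lipid metabolism whatever their values; per comparison the 8 largest rises and falls (4 in the third) with groups apart, a mean of at least 5 CPM and a gene name of the letters-and-number form; and, in the first and second comparisons, up to 4 members with the smallest adjusted p of each list past the threshold or with at least 3 calls. From these a subset is described.

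Shares of counts were compared by exact two-sided permutation. The overlap of comparisons that share libraries was set against 100 simulated sets without change, drawn from the fitted means and dispersions, and against independent lists. For ratios of counts, exact 95% counting intervals were used. In simulated data 64, 70 and 66 genes were changed 1.5-fold, 2-fold and 4-fold in mutant vehicle, and 14665 genes passed the filter. The procedure recovered 20.3%, 51.4% and 87.9% of these changed genes in the first comparison and 12.5%, 52.9% and 92.4% in the second. False calls made up 9.32% and 7.02% of the calls there, and none were made in the third. No pair of replicate libraries was near sampling noise.

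Alternatives were RLE and upper quartile scaling, no filter and a filter of 5 CPM in 3 libraries, fits of the 6 libraries compared, DESeq2 1.42.0, a replicate block, length-scaled counts, limma on log2(TPM + 1) and on log2(deposited CPM + 1), and leaving out each library in turn. A covariate for the spermatogenesis level was added after seeing the data. Calculations also used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.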

Results

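Gene expression was measured by RNA sequencing of whole *Caenorhabditis elegans* at the fourth larval stage (L4), just before adulthood. The animals were wild type or carried the gk849 allele of *nhr-114*, a nuclear hormone receptor gene of the HNF4 family. Mothers had been given vehicle or 8 µM vitamin B12, the cofactor of methionine synthase and of methylmalonyl-CoA mutase. The 9 libraries formed 3 groups of 3, namely wild type with maternal vehicle, the mutant with maternal vehicle, and the mutant with maternal B12. Estimated counts summed to 16425225, 16353580 and 16397454 in the wild-type libraries, to 14461993, 16418988 and 16092600 in the mutant vehicle libraries, and to 16659895, 14770977 and 14746504 in the mutant B12 libraries. Of 20444 genes, 14795 were tested. The labels do not state that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The first principal component of log2 CPM (counts scaled to library size) held 58.9% of the variance, with mutant vehicle libraries at 60.0, 89.3 and 71.7, mutant B12 libraries at -45.0, -58.5 and -44.6, and wild type at -1.49, -31.1 and -40.2. Wild-type replicate 1 was thus the wild-type library nearest to the mutant vehicle libraries. The order of the 9 libraries on this component was exactly the reverse of their order by spermatogenesis level, within each group as well. That level ran from -1.57 to -0.46 in mutant vehicle and from -0.07 to 0.59 in wild type, and was higher in each B12 library. The component therefore cannot be assigned to genotype or maternal B12 alone.

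*nhr-114* (WBGene00003704, WBcel235 chromosome V, 4187202 to 4190008) was almost absent from both mutant groups. It had 6954, 8027 and 7436 counts in the wild-type libraries (446 ± 38.7 CPM, SD, n = 3). The mutant vehicle libraries had 3, 4 and 4 counts, and the mutant B12 libraries had 3, 2 and 4. Summed per group, wild type exceeded mutant vehicle by a ratio of 1896 (95% counting interval 1060 to 3799) and mutant B12 by 2240 (1180 to 4899); these intervals cover counting error only. Which part of the gene the allele removes is not given in the labels.

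The first comparison asked what loss of *nhr-114* changed without added B12, and genes of B12-linked metabolism are given first. *mtrr-1*, which encodes methionine synthase reductase (chromosome II, 9285975 to 9289132), fell from 720 ± 102 to 60.8 ± 1.44 CPM (SD, n = 3 each). *acdh-1*, the acyl-CoA dehydrogenase of the propionate shunt (chromosome I, 6497436 to 6499560), fell from 4277 ± 321 to 980 ± 80.0 CPM. The shunt breaks down propionate without B12, and all 5 of its tested genes fell, also when adjusted over the list alone, among them *ech-6* (log2 fold change -1.62 ± 0.07 SE), *hach-1* (-2.01 ± 0.11) and *hphd-1* (-1.34 ± 0.10). The median was -1.62 (camera adjusted p = 5.62e-06, and adjusted p = 0.278 with an estimated correlation). In the methionine cycle 2 of 11 genes rose and 6 fell, with the same counts adjusted over the list alone. Methionine synthase *metr-1* (chromosome II, 10926561 to 10931078) changed by -0.85 ± 0.12 and the S-adenosylmethionine synthetase *sams-1* (chromosome X, 11965962 to 11969893) by -0.56 ± 0.11. The transsulfuration enzymes *cbs-1* (2.34 ± 0.11) and *cth-1* (1.05 ± 0.12) rose. The list as a whole did not pass camera (adjusted p = 0.228, and adjusted p = 0.617 with an estimated correlation). In B12-dependent propionate breakdown, 1 of 7 genes rose and 2 fell, against 2 and 2 adjusted over the list alone. The falls were *mmaa-1* (-2.72 ± 0.13) and *cblc-1* (-2.27 ± 0.09), both of B12 handling. The mutase gene *mmcm-1* (chromosome III, 3903185 to 3907687) did not pass, at 145 ± 1.40 CPM in wild type and 136 ± 4.92 CPM in the mutant (edgeR, Benjamini-Hochberg adjusted p = 0.350). That list did not pass camera (adjusted p = 0.191, and adjusted p = 0.617 with an estimated correlation). Of 12 folate-cycle genes, 2 rose and 4 fell, the same as adjusted over the list alone, with the serine hydroxymethyltransferase *mel-32* at -1.70 ± 0.09 and the reductase *mthf-1* at -1.40 ± 0.09 (camera adjusted p = 0.228, and adjusted p = 0.617 with an estimated correlation).

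Lipid synthesis genes were higher in the mutant. Of 25 tested genes of fatty acid synthesis and the SBP-1 axis, 19 rose and 1 fell, the same as adjusted over the list alone (median log2 fold change 0.77, camera adjusted p = 7.64e-08, and adjusted p = 0.278 with an estimated correlation). The fatty acyl-CoA desaturase *fat-5* (chromosome V, 17725004 to 17726818) rose from 48.0 ± 12.5 to 923 ± 44.0 CPM, and its paralogs *fat-7* (chromosome V, 7151353 to 7153146) and *fat-6* (chromosome IV, 11913692 to 11915687) by 3.40 ± 0.13 and 1.70 ± 0.10. Counts shared between *fat-6* and *fat-7* make their separate values uncertain. *sbp-1*, the worm SREBP (chromosome III, 11428367 to 11442566), rose by 1.01 ± 0.08. All 8 tested desaturases and elongases of polyunsaturated fatty acids rose, also adjusted over the list alone (camera adjusted p = 6.27e-07, and adjusted p = 0.260 with an estimated correlation); that list shares *fat-2*, *fat-6* and *fat-7* with the previous one. Of 12 genes of phosphatidylcholine synthesis, 7 rose and 2 fell, against 8 and 2 adjusted over the list alone (median 0.40, camera adjusted p = 0.0257, and adjusted p = 0.581 with an estimated correlation). Choline kinase *ckb-2* (3.55 ± 0.16), the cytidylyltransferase *pcyt-1* (1.54 ± 0.09) and the phosphoethanolamine methyltransferase *pmt-1* (chromosome II, 5278090 to 5282523; 565 ± 42.0 to 1603 ± 220 CPM) rose, whereas *pmt-2* (chromosome V, 4628580 to 4635263) fell by 0.46 ± 0.08 on the log2 scale. Of 18 genes of fat storage and lipolysis, 11 rose and 5 fell, the same as adjusted over the list alone, with the perilipin *plin-1* at 1.95 ± 0.09 and the lipase *lipl-5* at 1.94 ± 0.12. That list did not pass camera (adjusted p = 0.0710, and adjusted p = 0.598 with an estimated correlation), except without mutant vehicle replicate 1 (0.0423). Of 28 beta-oxidation genes, 13 rose and 4 fell, against 14 and 5 adjusted over the list alone, led by *cpt-3* (3.93 ± 0.27) and *hacd-1* (1.78 ± 0.14). Their camera adjusted p was 0.0217, 0.0610 without wild-type replicate 1, and adjusted p = 0.598 with an estimated correlation.

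**Figure D1:**
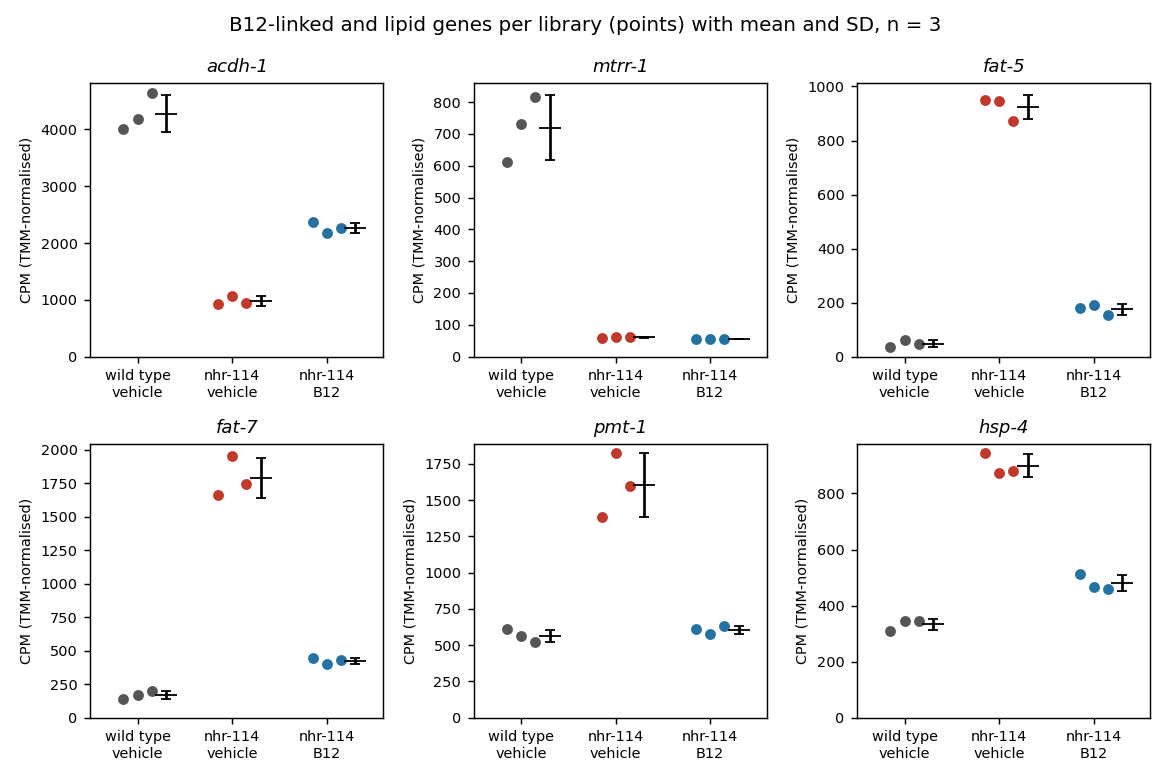
TMM-normalised CPM of 6 genes in each library (points, grey wild type with vehicle, red mutant with vehicle, blue mutant with maternal B12), with mean and SD of 3 libraries beside them. *fat-5*, *fat-7*, *pmt-1* and *hsp-4* were highest in mutant vehicle, *acdh-1* was lowest there, and *mtrr-1* was at 60.8 and 55.3 CPM in the mutant groups against 720 CPM in wild type.

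In lists of stress and detoxification more genes rose than fell in the same animals. In the unfolded protein response of the endoplasmic reticulum 17 of 20 genes rose and none fell, against 17 and 1 adjusted over the list alone. The chaperone *hsp-4* (1.43 ± 0.08) and the sensors *ire-1* (0.94 ± 0.08) and *pek-1* (0.95 ± 0.09) were among them (median 0.49, camera adjusted p = 1.72e-06, and adjusted p = 0.260 with an estimated correlation). In the mitochondrial unfolded protein response 9 of 14 rose and 0 fell, the same as adjusted over the list alone, including *cdr-2* (3.27 ± 0.21) and the transcription factor *atfs-1* (1.00 ± 0.08; camera adjusted p = 0.00138, and adjusted p = 0.278 with an estimated correlation). Of 15 cytosolic heat shock genes 12 rose and 0 fell, against 13 and 0 adjusted over the list alone, with *hsp-16.2* at 3.26 ± 0.29 (camera adjusted p = 1.40e-04, and adjusted p = 0.387 with an estimated correlation). The small heat shock genes have near-identical copies, so their separate values are uncertain. Of 26 SKN-1 and oxidative stress genes 16 rose and 2 fell, the same as adjusted over the list alone, with the glutathione transferases *gst-38* at 3.44 ± 0.20 and *gst-7* at 2.12 ± 0.10 (camera adjusted p = 3.86e-04, and adjusted p = 0.278 with an estimated correlation). Of 29 xenobiotic cytochrome P450 genes 15 rose and 5 fell, against 17 and 7 adjusted over the list alone, with *cyp-33C8* at 4.13 ± 0.37 and *cyp-35B1* at -2.37 ± 0.25. Their camera adjusted p was 0.0164, 0.101 over genes with at least 5 CPM in 3 libraries, and adjusted p = 0.260 with an estimated correlation. Of 46 innate immunity effectors 23 rose and 10 fell, against 25 and 11 adjusted over the list alone. The lysozyme genes *lys-4* (chromosome IV, 11621429 to 11623174) and *ilys-5* changed by -5.05 ± 0.16 and -2.50 ± 0.12, and *dod-22* by 3.28 ± 0.15. The immunity list's camera adjusted p was 0.0490, between 0.0564 and 0.0951 without wild-type replicate 1, mutant vehicle replicate 2 or any single B12 library, and adjusted p = 0.581 with an estimated correlation. Of 16 DAF-16 class I targets 6 rose and 3 fell, and of 13 genes of glutathione peroxidases, ferritin and iron 6 rose and 1 fell, against 7 and 3, and 6 and 2, adjusted over the list alone. These 2 lists did not pass camera (adjusted p = 0.118 and 0.0684, and adjusted p = 0.598 and 0.462 with an estimated correlation) and passed fry (0.0178 and 0.00277). Of 77 ribosomal protein genes 26 rose and 1 fell, the same as adjusted over the list alone, by small amounts (median 0.19, camera adjusted p = 1.88e-04, and adjusted p = 0.624 with an estimated correlation). With the spermatogenesis level of each library as a covariate, chosen after seeing the data, 0 of them were called. Their median was then -0.02 (camera adjusted p = 0.816, and adjusted p = 0.996 with an estimated correlation).

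The largest single rises were *dod-21* and its neighbour *cld-1* (chromosome IV, 12936738 to 12937988 and 12935011 to 12936271). *dod-21* had 3 counts over the wild-type libraries and 10345 over the mutant vehicle libraries, a ratio of 3707 (95% counting interval 1268 to 17976). *cld-1* rose by 8.79 ± 0.47 on the log2 scale. *sdz-35* (6.88 ± 0.29), *warf-1* (6.29 ± 0.24), *delm-2* (5.61 ± 0.37), *fat-5* (4.27 ± 0.18), *cyp-33C8* and *cdr-4* (4.00 ± 0.24) followed. After *nhr-114* itself, the largest falls were *clc-24* (1735 counts in wild type and 5 in the mutant, a ratio of 323 with interval 138 to 996), the C-type lectin *clec-47* (-5.66 ± 0.11), the lysozymes *lys-6*, *lys-4* and *lys-5*, the methionine sulfoxide reductase *msra-1* (-5.28 ± 0.16) and the ABC transporter *pmp-5* (-4.48 ± 0.16).

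Spermatogenesis genes were lower in the mutant, and lists of cuticle and epidermis went both ways. Of 68 spermatogenesis genes 55 fell and 0 rose, against 60 and 1 adjusted over the list alone, with *ssp-10* at -1.92 ± 0.28 and *spe-10* at -1.84 ± 0.25 (median -1.40, camera adjusted p = 1.96e-13, and adjusted p = 0.462 with an estimated correlation). Their share of all counts was 0.167% ± 0.0456 in wild type and 0.0618% ± 0.0266 in the mutant (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give, and 0.164 after Benjamini-Hochberg adjustment over 18 tests of class shares). The major sperm protein genes on the list are near-identical, so their separate values are uncertain. Of 14 markers of adult hypodermis and vulva 1 rose and 7 fell, the same as adjusted over the list alone, with the collagens *bli-1* and *col-38* at -1.80 ± 0.15 and -1.80 ± 0.25 (camera adjusted p = 0.0269, and adjusted p = 0.462 with an estimated correlation). Of 102 cuticle collagens 13 rose and 27 fell, against 15 and 27 adjusted over the list alone. The list's median and mean were positive, at 0.03 (-0.05 with upper quartile scaling) and 0.28, and the test leaned downward (camera adjusted p = 0.864, and adjusted p = 0.959 with an estimated correlation). Of 34 molting factors 6 rose and 14 fell, the same as adjusted over the list alone, with *mlt-10* at -2.24 ± 0.25. The molting list's camera adjusted p was 0.0526, between 0.0233 and 0.0447 without wild-type replicate 3, mutant vehicle replicate 1 or B12 replicate 1 or 3, and adjusted p = 0.617 with an estimated correlation. Of 6 vitellogenins, the yolk proteins, 3 fell and 0 rose, against 4 and 0 adjusted over the list alone, with *vit-6* at -2.66 ± 0.38 (camera adjusted p = 0.103, 0.0413 without wild-type replicate 1, and adjusted p = 0.617 with an estimated correlation). Of 15 markers of hypodermis and seam 5 rose and 5 fell, the same as adjusted over the list alone, with *wrt-2* at -1.19 ± 0.18 and *dpy-13* at -1.17 ± 0.20. Their median was -0.20 and their mean 0.33, opposite in sign (camera adjusted p = 0.728, and adjusted p = 0.928 with an estimated correlation). Of 20 intestine markers 10 rose and 2 fell, against 12 and 4 adjusted over the list alone, with *pgp-1* at 1.84 ± 0.13, *pho-1* at 0.75 ± 0.09 and the protease *cpr-4* at -1.55 ± 0.20. The intestine list (median 0.37) had a camera adjusted p of 0.0603, between 0.0206 and 0.0398 without wild-type replicate 2 or mutant vehicle replicate 1 or 3, and adjusted p = 0.598 with an estimated correlation. In other tissues 2 of 22 markers passed for body-wall muscle, 4 of 34 for neurons and 1 of 20 for pharynx, against 2, 3 and 0 adjusted over the list alone (camera adjusted p = 0.544, 0.666 and 0.643, and adjusted p = 0.928, 0.940 and 0.928 with an estimated correlation). For the somatic gonad 2 of 11 rose and 2 fell, and of 9 male-enriched markers 3 rose and 3 fell, against 2 and 2, and 4 and 3, adjusted over the list alone (camera adjusted p = 0.521 and 0.864, and adjusted p = 0.617 and 0.940 with an estimated correlation). The shares of these lists were not tested against each other.

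In all, edgeR called 5421 genes between mutant vehicle and wild type at a Benjamini-Hochberg adjusted p under 0.05, of which 2713 were higher and 2708 lower in the mutant. The share of higher calls was 42.2% with upper quartile scaling and 40.7% with limma on TPM. At least 2-fold changes numbered 1090 up and 1712 down, and the groups did not overlap for 50.8% of the genes, where chance gives 10%. The preset-correlation camera test passed 14 of the 38 lists, 11 up and 3 down. It also passed 8 to 16 lists in the 9 other splits of these libraries, and with an estimated correlation it passed 0. The counts of members therefore only describe the lists. Of all tested genes 36.6% were called, and members of a list are correlated, so a count near that share does not set a list apart. With the spermatogenesis level of each library as a covariate, a choice made after seeing the data, 677 genes were called, 507 higher and 170 lower, and 10 of the 25 fatty acid synthesis genes rose with none falling. All 5 propionate shunt genes fell. Calls were lost in other lists: 6 endoplasmic reticulum and 2 mitochondrial unfolded protein response genes and 1 heat shock gene rose, with none falling. In phosphatidylcholine synthesis 3 rose and 1 fell (camera adjusted p = 0.0651). The covariate overlaps with these groups (variance inflation 4.00), so lost calls are uncertain.

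The second comparison asked what maternal B12 changed in the mutant, and lists of the propionate shunt, fatty acid synthesis, the unfolded protein responses, heat shock and spermatogenesis moved opposite to the mutation. *acdh-1* rose from 980 ± 80.0 to 2269 ± 91.1 CPM (SD, n = 3 each), and all 5 propionate shunt genes rose, also adjusted over the list alone (median 0.81, camera adjusted p = 0.00112, and adjusted p = 0.469 with an estimated correlation). *fat-5* fell from 923 ± 44.0 to 175 ± 20.3 CPM, *fat-7* by 2.07 ± 0.12 and *fat-6* by 0.86 ± 0.10 on the log2 scale. Of the 25 genes of fatty acid synthesis and the SBP-1 axis 2 rose and 21 fell, against 2 and 22 adjusted over the list alone, including *sbp-1* (-0.75 ± 0.08) and the acetyl-CoA carboxylase *pod-2* (-1.84 ± 0.15; camera adjusted p = 5.06e-07, and adjusted p = 0.350 with an estimated correlation). All 8 polyunsaturated fatty acid genes fell, also adjusted over the list alone, with *fat-2* at -1.81 ± 0.08 (camera adjusted p = 3.23e-05, and adjusted p = 0.350 with an estimated correlation). Of 12 phosphatidylcholine synthesis genes 10 fell and 0 rose, the same as adjusted over the list alone, with *pmt-1* at -1.40 ± 0.11 and *pmt-2* at -0.56 ± 0.08 (camera adjusted p = 4.27e-04, and adjusted p = 0.469 with an estimated correlation). In the methionine cycle 5 of 11 rose and 4 fell, the same as adjusted over the list alone, and *metr-1* fell further, by 1.27 ± 0.12 on the log2 scale. The median of that list was -0.14 and its mean 0.05, opposite in sign (camera adjusted p = 0.910, and adjusted p = 0.958 with an estimated correlation). *sams-1* changed by -0.41 ± 0.11 (edgeR, Benjamini-Hochberg adjusted p = 0.0140, and 0.0608 and 0.0524 without mutant vehicle replicate 2 or B12 replicate 1; over all alternatives it kept its direction). *mtrr-1* stayed low, at 55.3 ± 0.413 CPM with B12 (log2 fold change -0.14 ± 0.10, edgeR adjusted p = 0.293, and 0.04 with length-scaled counts, adjusted p = 0.848), and *mmcm-1* did not pass (-0.09 ± 0.07, edgeR adjusted p = 0.343; -0.24 with limma on TPM, adjusted p = 0.0224).

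Lists of the unfolded protein and heat shock responses fell with maternal B12. The other stress and defence lists did not pass camera, though some passed fry. Of 20 endoplasmic reticulum unfolded protein response genes 17 fell and 0 rose, the same as adjusted over the list alone, including the chaperone *enpl-1* (-1.16 ± 0.09) and the sensor *ire-1* (-0.97 ± 0.08; camera adjusted p = 1.83e-06, and adjusted p = 0.350 with an estimated correlation). Of 14 mitochondrial unfolded protein response genes 9 fell and 0 rose, against 10 and 0 adjusted over the list alone, with *cdr-2* at -2.73 ± 0.20 (camera adjusted p = 0.00112, and adjusted p = 0.350 with an estimated correlation). Of 15 cytosolic heat shock genes 11 fell and 0 rose, the same as adjusted over the list alone, with *hsp-16.2* at -2.68 ± 0.28 and *hsf-1*, their transcription factor, at -0.57 ± 0.09 (camera adjusted p = 0.00512, and adjusted p = 0.521 with an estimated correlation). With the spermatogenesis level as a covariate, chosen after seeing the data, 0 heat shock genes were called (camera adjusted p = 0.158, and adjusted p = 0.746 with an estimated correlation). That fit called 2 endoplasmic reticulum and 1 mitochondrial response genes, all lower (camera adjusted p = 5.51e-06 and 0.0155, and adjusted p = 0.286 and 0.352 with an estimated correlation). Of 26 SKN-1 and oxidative stress genes 4 rose and 12 fell, against 4 and 14 adjusted over the list alone (camera adjusted p = 0.188, and adjusted p = 0.668 with an estimated correlation). Of 29 xenobiotic cytochrome P450 genes 8 rose and 12 fell, against 10 and 13 adjusted over the list alone (camera adjusted p = 0.242, and adjusted p = 0.521 with an estimated correlation). Of 16 DAF-16 class I targets 3 rose and 7 fell (camera adjusted p = 0.103). Of 13 genes of glutathione peroxidases, ferritin and iron 2 rose and 4 fell (camera adjusted p = 0.342). The P450, DAF-16 and glutathione lists passed fry (adjusted p = 1.24e-04, 0.00464 and 0.0205). The SKN-1 and immunity lists did not pass fry (0.0568 and 0.646). Of 46 innate immunity effectors 15 rose and 14 fell, against 16 and 15 adjusted over the list alone, with a median of 0.05 and a mean of -0.12, opposite in sign (camera adjusted p = 0.890, and adjusted p = 0.958 with an estimated correlation). Of 17 metabolic nuclear hormone receptors 1 rose and 11 fell, against 1 and 12 adjusted over the list alone, with *nhr-49* at -1.15 ± 0.08 and *nhr-80* at -0.87 ± 0.12 (camera adjusted p = 0.00224, and adjusted p = 0.392 with an estimated correlation). Of 20 intestine markers 2 rose and 14 fell, against 2 and 17 adjusted over the list alone, with the transporter *pgp-1* at -2.50 ± 0.14 and the protease *cpr-5* at -1.84 ± 0.25 (camera adjusted p = 0.00184, and adjusted p = 0.484 with an estimated correlation). Of 10 genes of tryptophan and kynurenine breakdown 7 rose and 0 fell, the same as adjusted over the list alone, with the dioxygenase *tdo-2* at 1.65 ± 0.17 and *umps-1* at 1.93 ± 0.18 (camera adjusted p = 0.00227, and adjusted p = 0.350 with an estimated correlation).

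Most sperm and yolk genes rose with maternal B12, and more collagen and oogenesis genes rose than fell. Of 68 spermatogenesis genes 62 rose and 1 fell, against 63 and 1 adjusted over the list alone, with *spe-10* at 2.40 ± 0.25 (median 1.94, camera adjusted p = 4.71e-16, and adjusted p = 0.469 with an estimated correlation), and their share of counts reached 0.217% ± 0.0240 (SD, n = 3). Of 102 cuticle collagens 50 rose and 16 fell, against 52 and 20 adjusted over the list alone, with *col-71* at 2.62 ± 0.23 and *dpy-4* at 1.98 ± 0.19 (median 1.43, camera adjusted p = 2.96e-04, and adjusted p = 0.647 with an estimated correlation). Collagens took 3.31% ± 0.433 of counts in mutant vehicle and 7.78% ± 1.08 with B12 (exact two-sided permutation p = 0.1, the smallest possible, 0.164 after Benjamini-Hochberg adjustment, higher in 3 of 3 libraries). Of 6 vitellogenins 5 rose and 0 fell, the same as adjusted over the list alone, with *vit-6* at 3.57 ± 0.39 (median 3.27, camera adjusted p = 0.00409, and adjusted p = 0.521 with an estimated correlation). Of 26 oogenesis genes 10 rose and 1 fell, against 9 and 1 adjusted over the list alone, with the eggshell gene *perm-2* at 2.94 ± 0.42 (camera adjusted p = 0.00224, and adjusted p = 0.668 with an estimated correlation). With the spermatogenesis level of each library as a covariate, chosen after seeing the data, the direction of the oogenesis list turned. Its median went from 0.62 to -0.47 (camera adjusted p = 0.0235, and adjusted p = 0.746 with an estimated correlation). edgeR then called 0 oogenesis genes, with 0 higher and 2 lower at an unadjusted p under 0.05. In that fit the collagen median was 0.44, and edgeR called 0 collagens, with 12 higher and 3 lower unadjusted. It called 0 vitellogenins, with 1 higher and 0 lower unadjusted, at a median of 2.90. The largest rises were *pud-4* (chromosome V, 2326678 to 2327282; 7.33 ± 0.45), *pud-3* (6.93 ± 0.45), *vit-3* (6.70 ± 0.81) and *pud-1.2* (6.28 ± 0.60), whose near-identical relatives make the separate values uncertain. The largest falls were *dod-21* (-7.48 ± 0.39), *cld-1* (-7.38 ± 0.43), *sdz-35* (-5.83 ± 0.27) and *warf-1* (-5.26 ± 0.23).

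**Figure D2:**
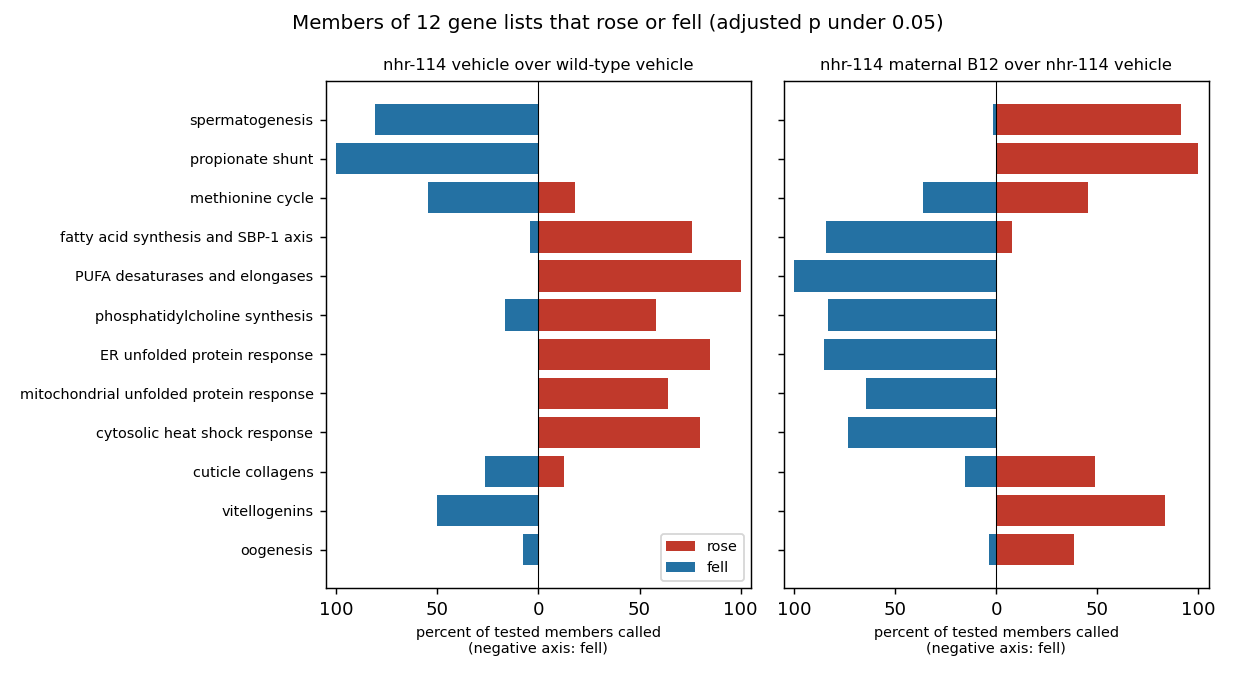
Percent of the tested genes of 12 lists that rose (red, to the right) or fell (blue, to the left) at an edgeR Benjamini-Hochberg adjusted p under 0.05. The left panel sets mutant vehicle against wild type and the right panel mutant B12 against mutant vehicle; for spermatogenesis, 55 of 68 genes fell in the first and 62 rose in the second.

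With edgeR, 6866 genes were called between mutant B12 and mutant vehicle at a Benjamini-Hochberg adjusted p under 0.05, 3338 higher and 3528 lower with B12, and 2203 and 1256 of them by at least 2-fold. The groups did not overlap for 59.1% of the genes, where chance gives 10%. Higher calls were 48.6% of all calls, but 35.9% with limma on TPM, a scaling that moved the median of all genes by -0.14. Camera with the preset correlation passed 14 of 38 lists, 6 up and 8 down, against 8 to 16 in the 9 other splits and 0 with an estimated correlation. Of all tested genes 46.4% were called, and a list's count near that share does not set it apart. With the spermatogenesis level as a covariate, 138 genes were called, 14.5% of them higher. Since that level largely follows this comparison, a call lost in that fit does not show the absence of a change. List medians in that fit were 0.95 for the propionate shunt, -0.56 for the endoplasmic reticulum unfolded protein response and -0.44 for fatty acid synthesis, against 0.81, -0.56 and -0.75 without the covariate. It called 1 shunt gene higher, and 2 and 3 genes of the other lists lower. For heat shock, metabolic nuclear hormone receptors and tryptophan breakdown it called 0 genes, with medians of -0.36, -0.42 and 0.96 against -0.43, -0.66 and 0.73 without it.

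The third comparison set mutant B12 against wild-type vehicle, which differ in genotype and in maternal B12 at once. More cuticle collagens were above wild type than below it, with 40 of 102 higher and 8 lower, against 57 and 10 adjusted over the list alone (median 0.95, camera adjusted p = 3.27e-08, and adjusted p = 0.749 with an estimated correlation), and 7.78% ± 1.08 of counts against 5.01% ± 0.607 (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). All 5 propionate shunt genes stayed below wild type, also adjusted over the list alone, with *acdh-1* at -0.91 ± 0.09 and *hphd-1* at -0.55 ± 0.10 (camera adjusted p = 1.18e-05, and adjusted p = 0.749 with an estimated correlation). *mtrr-1* (-3.70 ± 0.11), *metr-1* (-2.13 ± 0.12), *sams-1* (-0.97 ± 0.12) and *pmt-2* (-1.02 ± 0.08) were below wild type. *fat-5* (1.87 ± 0.17), *fat-7* (1.34 ± 0.12) and *fat-6* (0.84 ± 0.10) were above it. *pmt-1* did not pass, at 606 ± 28.4 CPM against 565 ± 42.0 (log2 fold change 0.10 ± 0.11, edgeR Benjamini-Hochberg adjusted p = 0.587, and -0.15 with limma on TPM). *sbp-1* changed by 0.25 ± 0.08 (edgeR adjusted p = 0.0576, and 0.0215 to 0.0376 with length-scaled counts, DESeq2 or a filter of 5 CPM). *mmcm-1* changed by -0.17 ± 0.07 (edgeR adjusted p = 0.130, and 0.00459 and 0.0332 with limma on TPM or on the deposited CPM). Of 46 innate immunity effectors 17 were higher and 7 lower, against 22 and 10 adjusted over the list alone (camera adjusted p = 0.00415, and adjusted p = 0.749 with an estimated correlation). Of 68 spermatogenesis genes 2 were higher, against 0 adjusted over the list alone (median 0.34, camera adjusted p = 8.35e-04, 0.0780 without wild-type replicate 1, and adjusted p = 0.749 with an estimated correlation). Of 27 replication-dependent histones 4 were lower and 0 higher, the same as adjusted over the list alone (camera adjusted p = 8.35e-04, and adjusted p = 0.749 with an estimated correlation). Ribosomal protein genes had 18 of 77 higher and 0 lower, against 25 and 0 adjusted over the list alone (median 0.18, -0.01 with limma on TPM; camera adjusted p = 1.70e-06, and adjusted p = 0.749 with an estimated correlation). The largest rises were *pud-3* (7.47 ± 0.47), *pud-4* (6.80 ± 0.43), the sphingomyelinase gene *asm-3* (6.42 ± 0.45) and *pud-1.2* (4.80 ± 0.55). After *nhr-114*, *clc-24* (-6.40 ± 0.40), *clec-47* (-5.42 ± 0.11) and *lys-6* (-4.70 ± 0.30) were lowest. edgeR called 1984 genes at a Benjamini-Hochberg adjusted p under 0.05, 1077 higher and 907 lower (673 and 685 higher without wild-type replicate 2 or B12 replicate 3, and 582 and 555 lower without B12 replicate 1 or 2). Limma on TPM called 4479, with 1574 shared in direction, moved the median of all genes by -0.24, and turned the share of higher calls from 54.3% to 16.9% (43.0% with limma on the deposited CPM). With the spermatogenesis level as a covariate 1087 genes were called. Camera passed 11 lists, against 3 to 9 in the 9 other splits and 0 with an estimated correlation. Of all tested genes 13.4% were called in this comparison.

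The changes of the mutant and those of maternal B12 were then set against each other gene by gene. Of the 5421 genes called between mutant vehicle and wild type, 4214 (77.7%) were also called between mutant B12 and mutant vehicle in the opposite direction, 2038 of them up and then down and 2176 down and then up. All 55 spermatogenesis genes that fell were among them, as were 19 of 20 called fatty acid synthesis genes, 16 of 17 called endoplasmic reticulum unfolded protein response genes and 33 of 40 called collagens. The counts were 1 of 27 for called ribosomal protein genes and 3 of 8 for called methionine cycle genes, and differences between lists were not tested. Both comparisons use the mutant vehicle libraries, and 100 simulated sets with no change gave 0.02 such genes on average (0 to 1), while independent lists of these sizes give 1258. Those sets gave no group a difference, so hardly any calls could arise. In 1 other split, with the mutant vehicle libraries kept together and the wild-type and B12 libraries mixed, 3491 such genes were called. A count near that size thus arises from the mutant vehicle libraries standing apart. How much of the excess comes from the shared libraries was not separated, since 3 libraries cannot be divided into sets of at least 2 to count these calls again. Across genes, which are not independent replicates, Pearson's r was -0.78 (simulated -0.50) and Spearman's rho -0.78 (simulated -0.47), and the covariance was -0.81 against a simulated -0.04. Since the simulated sets gave no group a difference, their values are no baseline for mutant vehicle libraries that stand apart. Of the 5421 genes, 3724 (68.7%) reversed and were not called against wild type, 203 reversed but were still called in the mutant's direction, and 287 were called on the other side of wild type. A further 459 were not called with B12 and stayed called in the mutant's direction. When each mutant vehicle library in turn was kept out of gene selection, the reversal slopes were 0.73, 0.87 and 0.74, a mean of 0.78. This slope is the distance of the kept-out library from mutant B12, per unit of the distance of the other mutant vehicle libraries from wild type. Those other libraries and wild type also selected the genes, which can enlarge that distance and lower the slope. The slope is therefore not an exact share of the change reversed. For 92.2% to 93.8% of the selected genes, mutant B12 differed from the kept-out mutant vehicle library in the direction of wild type. Larval age was not varied apart from the groups, so the slope does not separate it from maternal B12. With the spermatogenesis level as a covariate, the count of opposite calls was 127.

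**Figure D3:**
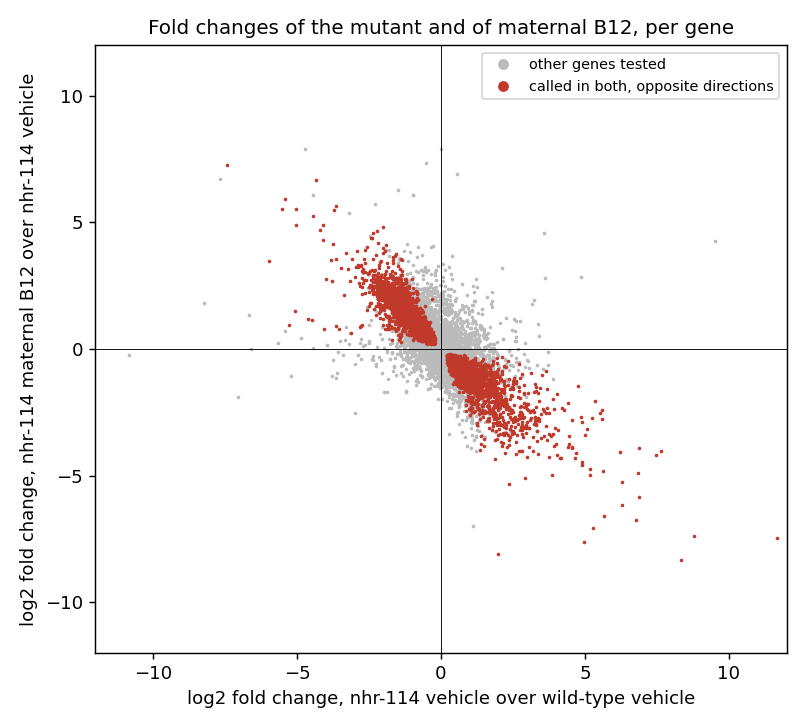
Log2 fold change of each of the 14795 tested genes between mutant vehicle and wild type (horizontal axis) and between mutant B12 and mutant vehicle (vertical axis). The 4214 genes called in both with opposite signs (red) fill the upper left and lower right. Across genes r was -0.78, against -0.50 in simulated sets with no change in any group. Those sets are no baseline for mutant vehicle libraries that stand apart, so the gap does not measure reversal by B12.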

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

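The tests with the spermatogenesis level as a covariate were chosen only after the results were seen, and the other alternatives were planned. Under RLE and upper quartile scaling, both filters, fits of 6 libraries, DESeq2, the replicate block, length-scaled counts and limma on the deposited CPM, the counts of changed genes and of opposite changes stayed within 1.5 times the reported ones. With limma on TPM the third comparison gave 4479 genes in place of 1984, of which 1574 were shared in direction, and the cause was not tested, although that scaling moved the median of all genes by -0.24. With the covariate the counts were 677, 138 and 1087 for the 3 comparisons and 127 for opposite changes. Between mutant vehicle and wild type the covariate overlaps with the groups by a variance inflation of 4.00. Between mutant B12 and mutant vehicle that inflation was not computed, and the level was higher in each B12 library than in any mutant vehicle library.

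Leaving out 1 library at a time, the counts ranged from 4193 to 5672 in the first comparison, from 5494 to 7085 in the second, from 1335 to 2117 in the third and from 3109 to 4428 for opposite changes. Without wild-type replicate 1, which stood nearest to the mutant vehicle libraries, they were 5557, 7085, 1727 and 4428. The correlation of fold changes ranged from -0.79 to -0.70, the latter without wild-type replicate 3, and the reversal slope from 0.71 to 0.80. Lists past camera ranged from 13 to 18, 14 to 16 and 9 to 15. With an estimated correlation 0, 0 and 0 lists passed, and with fry 24, 21 and 10. The germline list, not past in the third comparison, went from an adjusted p of 0.793 to between 0.0277 and 0.791 when 1 library was left out, with the lowest value, and the opposite direction, without B12 replicate 3; the cause was not tested.

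The replicate numbers showed no clear pairing of the samples. Of 9 correlations between same-numbered libraries of different groups 2 were over 0.1 (range -0.22 to 0.37). Libraries with different numbers gave -0.42 to 0.27. So few correlations cannot exclude pairing. The fit with the replicate block called 5153, 6617 and 1736 genes and 3999 opposite changes. *mtrr-1* between mutant B12 and mutant vehicle was 0.035 with length-scaled counts (adjusted p = 0.848, edgeR), and *pmt-1* between mutant B12 and wild type was -0.15 with limma on TPM (adjusted p = 0.226); neither passed the threshold before or after, and the cause was not tested. *nhr-114* kept its direction and side of the threshold in each alternative, and each of the 18 class shares kept its direction as a share of TPM. Over leave-one-out fits, named genes kept their direction and side of the threshold 2764 times and lost their call 62 times. In the simulation 2-fold changes were recovered in about 51.4% of genes in the first comparison, so a gene without a call is not shown to differ by less. Few genes were changed there, so this recovery need not hold for a comparison with 5421 calls.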

Other observations

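The tests of larval age and of shared paralog reads, and the choice of gene families by name, were made only after the results were seen. From 133 families of at least 10 tested genes with a common name, nuclear hormone receptor genes were picked after the data were seen. Families were not tested in other splits of the libraries. Of 189 tested *nhr* genes 102 were higher and 8 lower in mutant vehicle than in wild type (median log2 fold change 0.60), and 6 were higher and 122 lower with maternal B12 than in mutant vehicle (median -0.71). Against wild type, 2 were higher and 18 lower with B12. Camera gave an adjusted p of 1.14e-10 in the first comparison and adjusted p = 0.769 with an estimated correlation. The F-box family *fbxa* had 58 genes higher and 10 lower of 117 in mutant vehicle and 14 higher and 58 lower with B12. The *pals* family, known from the intracellular pathogen response, had 11 of 22 higher and 1 lower, then 1 higher and 11 lower (camera adjusted p = 1.40e-06 and 0.00704 for the 2 families in the first comparison, and adjusted p = 0.769 for each with an estimated correlation). These directions of the first and second comparisons held under each scaling.

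Glutathione transferase genes did not follow that course. Of 35 *gst* genes 18 were higher and 2 lower in mutant vehicle than in wild type, 9 rose and 9 fell with B12, and 17 were higher and 1 lower in mutant B12 than in wild type (median 0.69, camera adjusted p = 8.45e-08, and adjusted p = 0.939 with an estimated correlation). Neprilysin-like *nep* genes had 11 of 21 lower and 1 higher in mutant vehicle, and 13 higher and 1 lower with B12. Of 11 *irld* genes 7 were lower and 0 higher, then 8 higher and 0 lower (camera adjusted p = 0.00452 for *nep* and 0.00859 for *irld* in the first comparison, and adjusted p = 0.769 for each with an estimated correlation). All 28 tested *msp* genes fell in mutant vehicle and all 28 rose with B12, with 0 called against wild type; their near-identical sequences make them far fewer than 28 independent measurements.

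The spermatogenesis list was lower in mutant vehicle than in either other group. A difference in larval age at harvest was tested on genes of molting and cuticle collagens, which change within the L4 stage. These were called more often than other genes between mutant B12 and mutant vehicle, with an odds ratio of 2.35 (95% interval 1.63 to 3.45; 66.9% against 46.2% of genes), against 1.37 (0.958 to 1.95) between mutant vehicle and wild type and 6.08 (4.26 to 8.66) between mutant B12 and wild type. These intervals treat genes as independent, but members of these lists are correlated (estimated at 0.18 for molting factors and 0.24 for collagens). The intervals can thus be too narrow and do not measure the spread between samples. Of the 136 genes 64 were higher and 27 lower in mutant B12 than in mutant vehicle, 19 higher and 41 lower in mutant vehicle than in wild type, and 48 higher and 17 lower in mutant B12 than in wild type. An age difference of mutant vehicle alone would leave the last of these without account. Larval age and a direct effect of genotype or B12 on the germ line or cuticle both stay open, since the design does not vary age apart from the groups.

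The fatty acid synthesis list was higher in mutant vehicle than in wild type. With the spermatogenesis level as a covariate, the list's mean difference went from 0.94 ± 0.05 to 0.74 ± 0.04 (SE; 95% interval with the covariate 0.65 to 0.83), and its median from 0.77 to 0.39. The spermatogenesis level ran from -1.57 to -0.46 in mutant vehicle and from -0.07 to 0.59 in wild type, without overlap. The adjusted difference thus rests on a straight-line fit carried beyond each group's levels, and not on libraries at a shared level. How closely that level tracks larval age is also not known, so the adjusted difference cannot decide whether age is the whole cause. In that fit 10 of the 25 genes rose in place of 19, while the overlap of that level with these 2 groups inflates the variance 4.00 times at a given residual spread. For reads shared between *fat-5*, *fat-6* and *fat-7*, the values argue against that explanation. Their summed CPM was 5.33-fold higher, with the highest wild-type library at 1081 and the lowest mutant library at 4861. Of the 22 other genes 16 rose and 1 fell. Larval age stays open as the whole or a part of the cause, and so does genotype, since the design does not vary age apart from the groups.

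Some genes were called in the same direction against wild type in both mutant groups. Sequence differences linked to *nhr-114* in the mutant strain could leave such genes near it: within 2 Mb of *nhr-114* 39 of 520 genes (7.50%) were of this kind against 5.04% elsewhere, an odds ratio of 1.53 (95% interval 1.06 to 2.14). Chromosome V as a whole had an odds ratio of 1.35 (1.13 to 1.60), and the window against the rest of that chromosome 1.24 (0.836 to 1.80). These intervals treat genes as independent and do not measure the spread between samples. The excess near the gene is what linked variants would give, but it is not resolved from the rest of chromosome V, and both stay open.

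Other splits of the libraries were counted for each fitted result. For changed genes, 1 of the 10 splits of 6 libraries, the real one, gave as many in each comparison, with 5421, 6866 and 1984 genes against at most 0, 0 and 1 in the others, and 10 splits are too few for a share under 0.05. Unadjusted p under 0.05 was reached by 6728, 7861 and 4147 genes in the real splits. For gene lists past camera, 6, 4 and 1 of the 10 splits gave as many, with 14, 14 and 11 lists against at most 16, 16 and 9, which again is too few splits for a share under 0.05. For genes changed in opposite directions, 1 of 100 drawn splits of the 9 libraries, the real one, gave as many (4214). Nearly all draws broke up the mutant vehicle libraries, so this share cannot exclude chance for the reversal. The highest other gave 3491 and was the 1 other drawn split that kept the 3 mutant vehicle libraries together as the shared group, and the remaining 98 gave at most 0, so the count follows the mutant vehicle libraries standing apart.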
